A study of Drosophila melanogaster with 76 samples.

How the data were processed

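The study measured where 5 proteins sit on chromatin by ChIP-seq in Drosophila melanogaster embryos labelled 1–1.5 h and 2.5–3 h and in larvae labelled 48AEL. Per the labels, embryos were fixed with formaldehyde, ChIP reactions were run in duplicate with a magnetic-bead kit, and libraries were made for MGI sequencers. Whether the duplicates came from separate collections is not stated. The name IntS11 mislocalized stands in the titles of both the wild-type and the mutant embryo samples, so wild type and mutant were read from the words WT and Mutant in the titles. The series has 76 samples in groups of 2. Peak lists of 40 samples were used, 36 from embryos and 4 from larvae, in 20 groups. The other 36 samples were not analysed here. They are input chromatin, Zelda and GAF after α-amanitin, Pol II in rescue and IntS11-knockdown experiments, and IntS11 in embryos with mislocalized IntS11.

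The deposited lists give the start and end of each called peak in base pairs on build dm6, in 3 columns, without summit, height, fold enrichment, p or q. The submitters' processing notes name Trimmomatic 0.39, Bowtie2 2.2.5, SAMtools 1.18, MACS2 2.2.7.1 and deepTools 3.5.1 without their order, thresholds or control libraries. Each list was checked to hold sorted intervals that do not overlap. The smallest gap between peaks exceeded the shortest peak by 1 to 4 bp in every list. The shortest peak measured 249 to 328 bp in wild-type embryo lists and 208 to 261 bp in mutant embryo lists, so the limits of the peak caller differed between lists. Its mean was lower in the mutant for each antibody and stage, but the ranges overlapped. A wild-type GAF list at 2.5–3 h had the same 249 bp as both mutant ones. The lists hold no reads, so depth per library was unknown, and no interval or limit that needs it is given.

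Genes came from a table of the Release 6 assembly with 14238 records (13946 protein-coding, 260 microRNA and 32 snRNA), which gives start and end but no strand, exons or sequence. Peaks on 2L, 2R, 3L, 3R, 4, X and Y were used. A gene counted as bound when a peak of both lists of a group overlapped the 500 bp either side of its start or end. Regions were formed for each group of a comparison, as merged peaks that both of its lists overlapped by at least 1 bp. Lost and kept regions were counted over those of the first group, and gained ones over those of the second. A region was lost with peaks in both lists of the first group and neither of the second, gained in the opposite case, and kept with peaks in all 4. Leaving out a list loosens the rules for lost and gained, which raises these counts by construction. Chance overlap came from 100 circular shifts. For the regions of a comparison, only replicate 1 of the second group was shifted. The share of wild-type Pol II peaks near gene ends at 2.5–3 h, 61.3% in replicate 1 against 25.1% in shifted copies, was used to check that lists and genes share coordinates.

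Numbers of peaks, covered length and location shares were compared by two-sided exact permutation of the genotype within antibody and stage, on the log2 scale for numbers and lengths. With 2 lists against 2 the smallest p is 0.333, with both stages of 1 antibody 0.0556, with 2 antibodies 0.00154 and with all 4 1.19e-06. Tests of a difference between antibodies or stages have as null no genotype effect in any of them. The orders treat antibodies as independent, and whether lists of different antibodies share chromatin is not stated. Genes of 26 lists were compared by two-sided Fisher's exact tests, adjusted by Benjamini-Hochberg over the lists of a comparison at 0.05. Loss was set against all other bound genes, gain against other genes not bound in the first group, and wild-type occupancy against other genes. These are p-values adjusted over the lists alone. Of 576 symbols asked for, 4 found no gene record. Peak lengths and gene lengths of lost and kept items were compared with 100000 permutations over peaks or genes, in which the smallest p is 1e-05. Odds ratios within quartiles of wild-type peak length were combined by the Mantel-Haenszel method. The groups, comparisons, tests, gene lists and the rule for naming genes were chosen before the data were examined.

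Several parts of the plan were replaced because the lists hold positions only. Peak length took the place of fold enrichment as the measure of strength, and windows at both gene ends took the place of promoters. Thresholds on q were replaced by a minimum of 500 bp and by the longest peaks up to the shortest list of a comparison. A test of motifs and a test of genes without introns were not run, since no sequence and no exons were at hand. Alternatives chosen after seeing the data were lists harmonised by joining intervals up to 330 bp apart and leaving out joined intervals under 330 bp, the chromosome arms alone, whole genes with 500 bp either side, and leaving single replicates or histone genes out of the gene-level tests. Also chosen then were the centromere-proximal windows, 2L from 22 Mb, 2R to 6 Mb, 3L from 23 Mb, 3R to 5 Mb and X from 22 Mb, with windows 1 Mb larger as their alternative. Alternatives chosen before were windows of 250 and 1000 bp, overlap of 50% of the shorter interval, either replicate, lists of all sequences, replicate numbers as a block, and leaving out each replicate of the numbers and regions.

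Genes were named by rank of the mean percentile of peak length in their own lists, the first 8 lost, 6 kept and 6 gained per comparison with a gene name, and up to 4 members of each list with at least 3 bound genes. Regions named by coordinates outside genes were chosen after their values were seen. The result at one gene with loss of pSer5 is not reported here.

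The calls were tested on simulated data built from the same lists, 50 simulations per comparison. Planted gene lists were called in 98% to 100% and unplanted ones in 0% to 4% of them, at an unadjusted Fisher's exact p under 0.05. These lists had a single size and fixed shares of loss. The rates thus do not describe adjusted calls for lists of other sizes or other shares of loss. The largest relative error in the number of regions of a class was 0.0941%. Simulated peaks were copies of wild-type regions with small shifts, gained ones lay apart from them, and no noise peaks were added. This error was thus small by construction. Computation used Python 3.11.15, NumPy 2.4.6, SciPy 1.17.1, statsmodels 0.14.6 and matplotlib 3.10.9.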

Results

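Peak lists from ChIP-seq of Drosophila melanogaster were compared between wild-type and mutant embryos of an experiment labelled IntS11 mislocalized. IntS11 is the RNA-cleaving subunit of Integrator, the complex that processes small nuclear RNAs and ends short transcripts of RNA polymerase II. The antibodies were against Zelda and GAF, DNA-binding factors that open chromatin in the early embryo, against RNA polymerase II (Pol II), and against its form phosphorylated on serine 5 (pSer5), a mark of early elongation. Embryos were labelled 1–1.5 h or 2.5–3 h, with 2 lists per antibody, stage and genotype. IntS11 was mapped in wild-type embryos at both stages, and Pol II in wild-type and zygotic-mutant larvae labelled 48AEL. Each of the 40 lists held between 1276 and 12202 peaks as positions without heights or reads, so sequencing depth was unknown. A region counted as lost when both wild-type lists and neither mutant list had a peak, as gained in the opposite case, and as kept when all 4 lists had one. The p-values for numbers, lengths and shares of peaks measure the spread between these lists, and those over genes or single peaks hold no spread between samples. Neighbouring genes under a shared peak, as in the repeated histone locus or the Enhancer of split complex, were counted separately. The p-values of such gene lists are therefore too small. Several gene lists also share members. The earliest zygotic list shares genes with the gap, pair-rule, dorsoventral, sex determination and cellularization lists, so their calls are not independent.

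Zelda peaks were fewer in mutant embryos at both stages. At 1–1.5 h the mean fell from 11342 ± 479 to 2772 ± 266 peaks (SD, n = 2 lists each), and at 2.5–3 h from 10890.5 ± 667 to 3993.5 ± 729. GAF peaks numbered 6246 ± 420 in wild type and 4690.5 ± 913 in the mutant at 1–1.5 h, and 8573.5 ± 691 and 4565.5 ± 1367 at 2.5–3 h. Over both stages and both factors, every mutant list was shorter than every wild-type list of its antibody and stage, with a mean log2 ratio of −1.21 (two-sided exact permutation within antibody and stage, p = 0.00154, the smallest possible here). Pol II and pSer5 did not change in 1 direction. Pol II numbered 7408.5 ± 442 peaks in wild type against 8515.5 ± 432 in the mutant at 1–1.5 h, then 9272.5 ± 285 against 5197.5 ± 991 at 2.5–3 h. The pSer5 lists held 8920 ± 820 and 11825 ± 533 peaks at 1–1.5 h, and 9493.5 ± 155 and 9250.5 ± 276 at 2.5–3 h. Their joint log2 ratio was −0.07 (exact permutation p = 0.625). It passed the exact permutation test as a fall with joined intervals (−0.63, p = 0.00309) and with peaks of at least 500 bp (−0.79, p = 0.00309). On the chromosome arms it was −1.34 (exact permutation p = 0.00154), but the centromere-proximal windows left out there held more of the mutant peaks, which lowers mutant numbers by construction. The difference from the Zelda and GAF ratio was 1.15 (exact permutation p = 0.00674). The null of that test is no genotype effect in any antibody or stage, so its p alone does not show that the classes differ. That difference did not pass 0.05 when intervals up to 330 bp apart were joined and shorter ones left out in every list (0.81, exact permutation p = 0.125), or on the chromosome arms alone (0.47, exact permutation p = 0.513). Joining also turned the higher Pol II and pSer5 numbers at 1–1.5 h into log2 ratios of −0.08 and −0.31. Within 1 antibody and stage, 2 lists against 2 cannot give an exact permutation p below 0.333.

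The length of DNA under peaks was shorter in mutant embryos for the 4 antibodies together. Zelda peaks covered 12.5 ± 1.08 Mb in wild type and 1.79 ± 0.192 Mb in the mutant at 1–1.5 h (SD, n = 2 lists each), and 11.4 ± 0.806 and 2.96 ± 0.587 Mb at 2.5–3 h. Pol II coverage was 3.05-fold less in the mutant at 2.5–3 h but 1.11-fold more at 1–1.5 h (7.03 ± 0.490 and 7.84 ± 0.807 Mb). Over the 8 comparisons the mean log2 ratio of covered length was −1.22 (exact permutation p = 1.31e-05), with −1.54 for Zelda and GAF (p = 0.00154) and −0.89 for Pol II and pSer5 (p = 0.00772). The difference between these classes did not pass the test (0.64, exact permutation p = 0.308).

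**Figure D1:**
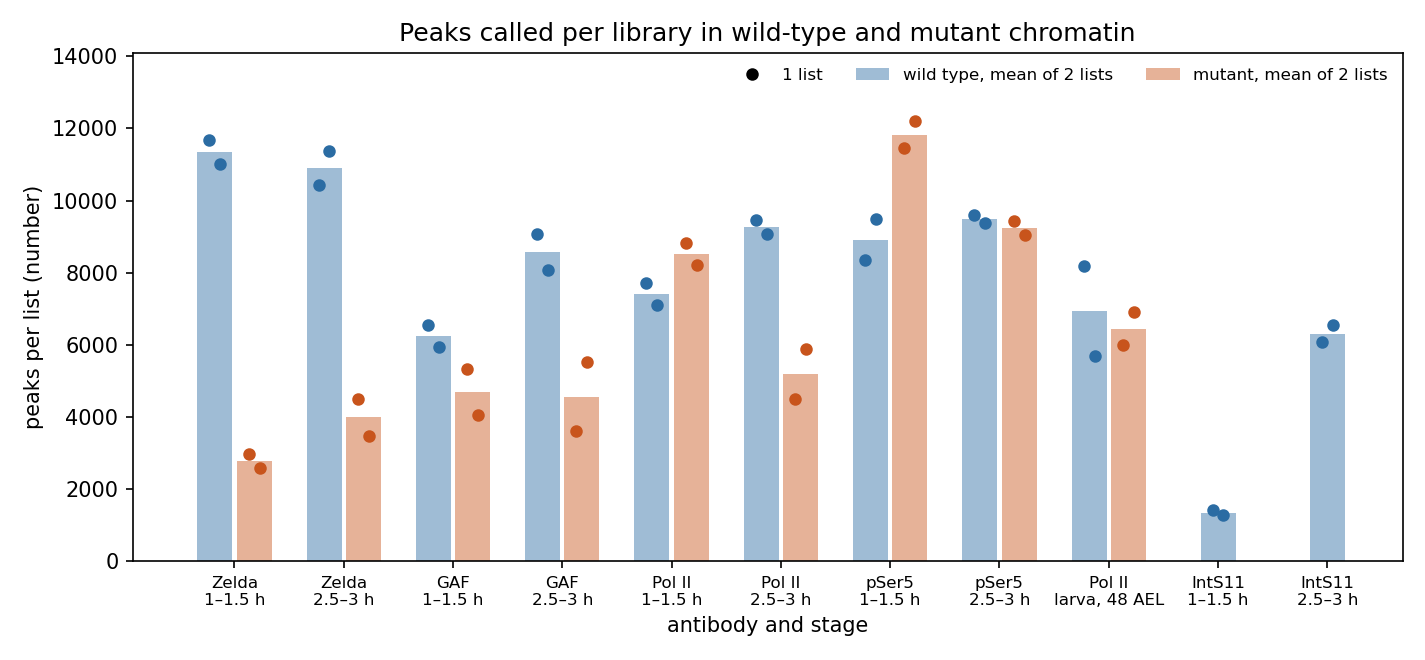
Number of peaks per list (y axis) by antibody and stage (x axis), with bars for the mean of 2 lists, points for single lists, blue for wild type and orange for mutant. Mutant Zelda lists hold 2772 and 3993.5 peaks on average against 11342 and 10890.5 in wild type, while IntS11 in wild type goes from 1343 to 6308.5 between the stages.

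Most of the regions that wild-type embryos bound had no peak in either mutant list, in each of the 8 comparisons. Of 8981 Zelda regions in both wild-type lists at 1–1.5 h, 5.12% were kept and 91.4% lost. Later, at 2.5–3 h, 13.5% of 8268 Zelda regions were kept and 78.1% lost. GAF kept 11.5% of 5070 regions at 1–1.5 h and 34.0% of 6521 at 2.5–3 h. Pol II kept 12.5% of 5763 regions at 1–1.5 h and 1.09% of 7089 at 2.5–3 h, with 97.8% lost. For pSer5 the kept shares were 9.10% of 6870 and 20.7% of 7662 regions. Replicate lists of these 4 antibodies overlapped by 78.9% to 88.3% in wild-type embryos and by 66.6% to 77.2% in mutant embryos. The other ways to part the 4 lists of a comparison into pairs gave at most 164 lost regions, against 3624 to 8207 by genotype. Wild-type Zelda regions at 1–1.5 h overlapped a single mutant list by 6.87% on average and randomly shifted copies of mutant replicate 1 by 3.74%. Here and below the overlap is a mean over both mutant lists, while shifted copies come from mutant replicate 1 alone. The 2 mutant lists can differ, as for GAF at 2.5–3 h, where replicate 1 alone was overlapped by 34.7%. Pol II regions at 2.5–3 h overlapped a mutant list by 1.64% and shifted copies by 5.26%, and at 1–1.5 h by 15.1% and 11.4%. Overlap and shifted copies gave 17.7% and 5.94% for Zelda at 2.5–3 h, 14.4% and 6.65%, then 39.2% and 4.91% for GAF at the 2 stages, and 13.0% and 15.7%, then 24.98% and 14.5% for pSer5. Keeping the longest peaks of each list so that all lists were equally long raised the kept share of Zelda to 16.8% and 32.1% at the 2 stages, and that of GAF at 2.5–3 h to 52.9%. Without mutant replicate 1 the Pol II share at 2.5–3 h was 2.12% and the pSer5 share at 1–1.5 h 13.8%. Without wild-type replicate 2 of GAF at 2.5–3 h, 5704 regions were lost in place of 3624. The direction of this change is fixed, since leaving out a list loosens the rule for lost regions.

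**Figure D2:**
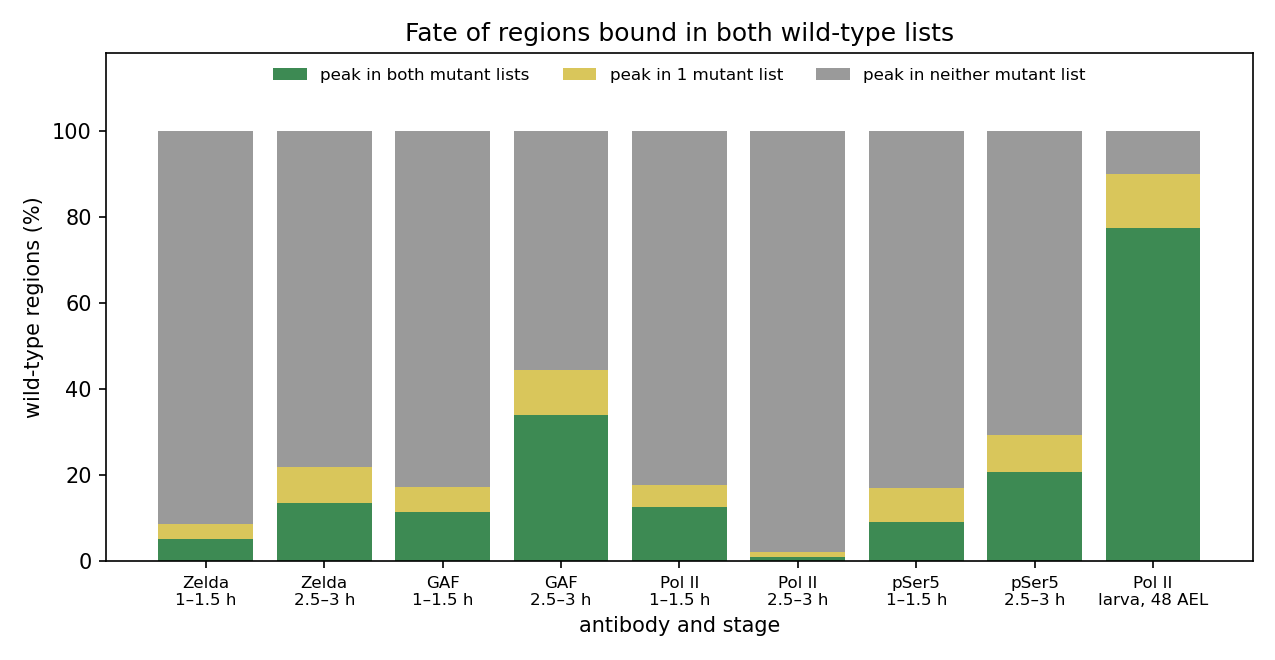
Share of the regions in both wild-type lists (y axis, %) that had a peak in both mutant lists (green), in 1 (yellow) or in neither (grey), by antibody and stage (x axis). Kept shares run from 1.09% to 34.0% in embryos, against 77.4% in larvae.

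The longest wild-type peaks were kept more often than short ones. In the first wild-type Zelda list at 1–1.5 h the median length was 2797 bp for kept and 802 bp for lost peaks, and for pSer5 at 2.5–3 h 2985 and 961.5 bp. Pol II differed least, with 1286 and 995 bp at 2.5–3 h. The probability that a kept peak was longer than a lost one lay between 0.587 for Pol II at 2.5–3 h and 0.851 for Zelda at 2.5–3 h (permutation over peaks, adjusted p between 1.12e-05 and 0.00596 over 18 tests, peaks not being replicates). Among the longest 10% of wild-type regions, Zelda kept 28.4% at 1–1.5 h and 66.6% at 2.5–3 h. GAF kept 49.5% and 87.9%, pSer5 30.4% and 71.6%, and Pol II 31.2% and 3.67%. Any overlap of 1 bp counted, so longer regions also meet mutant peaks more often by position alone. No chance level by length was drawn, so these values do not separate strength from length.

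Most genes with Zelda peaks in wild type at 1–1.5 h had none in mutant embryos, patterning genes among them. Of 6478 genes with a Zelda peak within 500 bp of an annotated end, 6202 (95.7%) had none in either mutant list. A wild-type peak at the Enhancer of split complex, whose genes answer to Notch signalling, was the longest of replicate 2 but not of replicate 1 (longest 23335 bp). Measuring 23099 bp and 37308 bp in the 2 lists, it spanned E(spl)m6-BFM, E(spl)m7-HLH and gro, a corepressor gene, which had no mutant peak at their ends, and E(spl)m4-BFM, E(spl)m5-HLH and E(spl)m8-HLH, where short mutant peaks of 724 and 1011 bp, 640 and 730 bp, and 559 and 453 bp remained. The gap gene Kr at 2R 25226611–25231394 lost peaks of 19890 and 13933 bp, the gap gene hb lost peaks of 12118 and 13595 bp, and slp1, a pair-rule gene, lost 13127 and 13945 bp. At ftz, a pair-rule gene at 3R 6864324–6866244, the peaks shrank from 12879 and 14397 bp to 713 and 645 bp. At Tom, a Bearded-family gene that restrains Notch signalling, they went from 12645 and 12825 bp to 611 and 963 bp. Loss was less frequent in lists of early zygotic genes than among the other bound genes. It took 7 of 16 earliest zygotic genes (Fisher's exact test, odds ratio 0.0341, adjusted p = 3.1e-08) and 4 of 15 Notch target and Bearded genes (odds ratio 0.0168, adjusted p = 1.05e-11). Pair-rule genes lost it at 4 of 9, gap genes at 8 of 12, dorsoventral genes at 14 of 21, cellularization genes at 3 of 8, early microRNA genes at 7 of 12 and sex determination genes at 4 of 7, with adjusted p from 4.44e-05 to 0.00681. Pioneer factor genes, lost at 5 of 8, did not pass with 250 bp windows (log2 odds ratio −2.51 against −3.85, adjusted exact p = 0.45) or without mutant replicate 1 (−3.49, adjusted p = 0.0700). Histone genes, near-identical copies in which reads cannot be placed with certainty, lost it at 31 of 96 (adjusted exact p = 4.25e-67). Segment polarity (9 of 9), Hox (7 of 8), heat shock (16 of 16), spliceosomal snRNA (23 of 24), ribosomal protein (71 of 72), proteasome (28 of 28), housekeeping (17 of 17), glycolysis (8 of 8), Integrator (6 of 7), maternal (7 of 9), muscle (6 of 6), neuronal (4 of 4), fat body (7 of 7) and ecdysone response genes (7 of 7) did not pass the test against other genes. No larval cuticle gene of 16 and no gut enzyme gene of 20 was bound in wild type.

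Zelda lay at several early zygotic genes of the mutant at 2.5–3 h, and its loss covered 5052 of 6070 bound genes (83.2%). At Kr a peak of 12806 and 17007 bp in wild type measured 1017 and 1219 bp in the mutant, and at ftz 22374 and 28263 bp became 4613 and 4197 bp. Peaks at slam, a gene for cell formation, went from 5880 and 6337 bp to 2168 and 2416 bp. The Hox gene Abd-B lost peaks of 9333 and 11904 bp, and Diap1, an inhibitor of cell death, lost 10214 and 10168 bp. All 15 bound Notch target and Bearded genes kept Zelda (odds ratio 0.00641, adjusted exact p = 2.79e-11), and the earliest zygotic genes lost it at 2 of 17 (odds ratio 0.032, adjusted p = 1.8e-09). Loss was also less frequent at pair-rule (1 of 9), cellularization (1 of 8), early microRNA (1 of 12), gap (4 of 12), segment polarity (2 of 8), dorsoventral (6 of 20), snRNA (12 of 25) and histone genes (31 of 78), with adjusted p up to 0.00118. The Hox genes, lost at 3 of 8 (adjusted exact p = 0.0111), did not pass with 250 bp windows (log2 odds ratio −1.27 against −2.97, adjusted p = 0.439) or without mutant replicate 2 (−1.87, adjusted p = 0.205). Ribosomal protein genes lost it at 65 of 72 and did not pass the test against other genes. No test was made of whether the lists differed between stages.

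Most genes with GAF peaks in wild type had none in mutant embryos, and at 2.5–3 h gap and segment polarity genes had them more often than other genes. At 1–1.5 h, 3528 of 4015 bound genes (87.9%) lost GAF, and at 2.5–3 h 2991 of 4487 (66.7%). Trl, the gene that encodes GAF, lost peaks of 8070 and 8921 bp at 1–1.5 h but at 2.5–3 h had 8283 and 8084 bp in wild type and 6893 and 8335 bp in the mutant. At trx, a chromatin activator gene, peaks of 10121 and 9929 bp shrank to 611 and 450 bp at 1–1.5 h, and measured 10021 and 10699 bp against 9942 and 10299 bp at 2.5–3 h. The Hedgehog receptor gene ptc had 6466 and 6121 bp against 1207 and 475 bp at 1–1.5 h, and 7131 and 8383 bp against 5500 and 7203 bp at 2.5–3 h. Loss at 2.5–3 h was less frequent at gap genes (1 of 13, odds ratio 0.0596, adjusted exact p = 0.000422) and segment polarity genes (1 of 8, adjusted p = 0.0112). It was more frequent at spliceosomal snRNA genes (24 of 24, odds ratio 24.7, adjusted exact p = 0.000796) and ribosomal protein genes (47 of 51, odds ratio 5.35, adjusted p = 0.000422). Histone genes lost it at 2 of 109 at 1–1.5 h (odds ratio 0.00251, adjusted exact p = 1.64e-98). The remaining calls ended under other settings. For gap genes at 1–1.5 h (7 of 13 lost, adjusted exact p = 0.0325) this was so without mutant replicate 1 (log2 odds ratio −1.17 against −2.66, adjusted p = 0.922), for sex determination genes (1 of 4, adjusted p = 0.042) without wild-type replicate 2 (−3.19 against −4.09, adjusted p = 0.0701), and for ribosomal protein genes (44 of 44, log2 odds ratio 3.64, adjusted p = 0.0417) without mutant replicate 1 (3.12, adjusted p = 0.257) or wild-type replicate 2 (3.52, adjusted p = 0.0528), where the odds ratio stayed nearly as large, and within quartiles of wild-type peak length (0.75, p = 0.455, with 0.5 added to each cell). Ecdysone response genes at 2.5–3 h (1 of 8 lost, adjusted exact p = 0.0112) did not pass without mutant replicate 2 (log2 odds ratio −1.41 against −3.33, adjusted p = 0.392), nor histone genes (51 of 105, adjusted p = 0.000886) with 250 bp windows (−0.72 against −1.11, adjusted p = 0.0980).

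Most genes with Pol II peaks in wild type at 1–1.5 h had none in mutant embryos, histone, snRNA, heat shock and early zygotic genes less often so. Of 6523 bound genes, 5417 (83.0%) lost it, including wech, a gene for muscle attachment, with wild-type peaks of 10146 and 6538 bp, and eIF4A, a translation factor gene, with 6821 and 6795 bp. At slp1, a pair-rule gene, peaks of 1280 and 1585 bp measured 1787 and 1777 bp in the mutant. The peak over the histone gene His1:CG33846 at 2L 21506684–21507706, within the repeated histone locus, went from 9709 and 9725 bp to 53781 bp in both mutant lists. None of 111 histone genes lost Pol II (Fisher's exact test, odds ratio 0.000824, adjusted p = 6.25e-87). Spliceosomal snRNA genes lost it at 5 of 26 (odds ratio 0.0513, adjusted exact p = 2e-11), heat shock genes at 4 of 18 (odds ratio 0.0626, adjusted p = 1.53e-07) and Notch target and Bearded genes at 2 of 15 (odds ratio 0.0374, adjusted p = 5.85e-08). The earliest zygotic genes lost it at 4 of 16 (adjusted exact p = 2.59e-06), pair-rule genes at 1 of 8 (adjusted p = 0.000117), dorsoventral genes at 7 of 16 (adjusted p = 0.00153), and gap genes at 6 of 12 and cellularization genes at 4 of 9 (both adjusted p = 0.0208). Early microRNA genes, lost at 6 of 12, did not pass with 250 bp windows (log2 odds ratio −1.67 against −2.30, adjusted exact p = 0.139). Sex determination genes, lost at 2 of 6, did not pass without mutant replicate 1 (log2 odds ratio −2.66 against −3.14, adjusted exact p = 0.0874) or 2 (−2.48, adjusted p = 0.107), nor did ribosomal protein genes, lost at 56 of 82, without mutant replicate 1 (−0.54 against −1.22, adjusted p = 0.414). Proteasome genes lost it at 29 of 31 and housekeeping genes at 12 of 17, and neither passed the test against other genes.

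Almost no gene with Pol II peaks in wild type at 2.5–3 h had them in both mutant lists. Pol II was lost at 7078 of 7370 genes (96.0%), among them the cell-cycle kinase gene Cdk1 with da and mRpS7 under 1 peak of 11277 and 11614 bp, the glycolysis gene Pgk with peaks of 10268 and 10234 bp, and ftz with 4919 and 3877 bp. The heat shock gene Hsp70Ba lost peaks of 3583 and 3555 bp. The snRNA genes lost Pol II at 25 of 26, heat shock genes at 15 of 16, ribosomal protein genes at 79 of 83, proteasome genes at 32 of 32, housekeeping genes at 16 of 16, pair-rule genes at 8 of 8 and gap genes at 11 of 12, and these lists did not pass the test against other genes. All 111 histone genes kept it (odds ratio 0.000115, adjusted exact p = 4.33e-165), though the peaks over His1:CG33846 went from 9710 and 9723 bp to 1485 and 909 bp. Histone genes lie in a repeated locus and several share a peak, so this p counts them as more independent than they are. Losses at 8 of 13 earliest zygotic genes and 7 of 15 Notch target and Bearded genes were below those of other genes (adjusted exact p = 0.00081 and 3.63e-07), but not without mutant replicate 2 (log2 odds ratios −2.44 against −3.99 and −2.22 against −4.82, adjusted p = 1 in both). The difference between stages was not tested per gene list. For the number of peaks, the log2 ratio at 2.5–3 h minus that at 1–1.5 h was −1.05 (exact permutation p = 0.0556, the smallest that 36 orders can give). The null is no genotype effect at either stage, so this p alone does not show a difference between stages.

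Loss of pSer5 peaks was less frequent at heat shock and ribosomal protein genes than at other genes at both stages. The form was lost at 5856 of 7591 genes (77.1%) at 1–1.5 h and at 5650 of 8632 (65.5%) at 2.5–3 h. At the heat shock gene Hsp70Aa peaks of 13092 and 14524 bp shrank to 1579 and 1913 bp at 1–1.5 h, and 18321 and 18374 bp to 2099 and 2086 bp at 2.5–3 h. At RpL11, a ribosomal protein gene, 15876 and 16225 bp became 297 and 292 bp at 1–1.5 h. Heat shock genes, some of them near-identical copies, lost pSer5 at 1 of 18 at each stage (odds ratio 0.0252 and 0.045, adjusted exact p = 2.19e-09 and 1.09e-06). Ribosomal protein genes lost it at 39 of 83 and 19 of 83 (odds ratio 0.258 and 0.157, adjusted p = 2.02e-08 and 3.16e-14), and histone genes at 0 of 111 at each stage (Fisher's exact test, adjusted p = 1.13e-71 and 3.85e-51). Loss at 2.5–3 h was also less frequent at Notch target and Bearded (0 of 15, adjusted exact p = 1.01e-06), earliest zygotic (2 of 15, adjusted p = 0.000248), segment polarity (0 of 7, adjusted p = 0.00253) and pair-rule genes (1 of 9, adjusted p = 0.00467). Other calls ended under other settings. Notch target and Bearded genes at 1–1.5 h (6 of 15 lost, adjusted exact p = 0.0139) and earliest zygotic genes (8 of 17, adjusted p = 0.0345) did not pass with whole genes in place of their ends (log2 odds ratios −1.40 against −2.31 and −1.68 against −1.92, adjusted p = 0.155 and 0.0730). Dorsoventral genes at 2.5–3 h (7 of 19, adjusted exact p = 0.0393) did not pass with 1000 bp windows (log2 odds ratio −1.36 against −1.66, adjusted p = 0.123), nor proteasome genes (13 of 34, adjusted p = 0.0053) without mutant replicate 2 (−1.06 against −1.60, adjusted p = 0.113). The snRNA genes lost pSer5 at 21 of 24 at 1–1.5 h and 13 of 27 at 2.5–3 h, without passing the test against other genes.

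Peaks of mutant embryos lay less often at gene ends and more often near the centromeres than those of wild type, for each of the 4 antibodies. In wild-type embryos 42.4% to 67.5% of the peaks of a list lay within 500 bp of an annotated gene end, and in mutant embryos 4.51% to 26.7%, so that the 20 wild-type and 16 mutant lists did not overlap. Pol II at 2.5–3 h went from 61.8% to 5.89%, Zelda at 1–1.5 h from 46.6% to 7.28% (means of 2 lists). Inside genes and away from their ends lay 36.7% of mutant Pol II peaks and 49.5% of mutant pSer5 peaks at 2.5–3 h, against 31.5% and 34.1% in wild type, and outside genes 57.4% and 26.6%, against 6.64% and 6.67%. In shifted copies of a wild-type Pol II list 25.1% of the peaks lay near gene ends on average. No shifted value was drawn for peaks inside or outside genes. The mean change in the share near gene ends over the 8 comparisons was −41.1 points (exact permutation p = 1.19e-06, the smallest that its 1679616 orders can give). This p treats the antibodies as independent, and it is too small if their lists came from shared chromatin, which is not stated. Windows next to the centromeres, chosen after the peaks were seen, held 13.9% of the genome and 2.28% of its genes. They held 2.07% to 12.8% of the peaks of wild-type embryo lists and 19.2% to 66.0% of those of mutant embryo lists, 37.6 points more on average (exact permutation p = 1.19e-06). On the arms outside these windows, Pol II peaks were fewer at 1–1.5 h too (log2 ratio −1.59), and the 4 antibodies together fell by 1.58 on the log2 scale (exact permutation p = 1.19e-06). As the windows held more of the mutant peaks, leaving them out lowers mutant numbers by construction, so these values are no separate support for a fall.

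**Figure D3:**
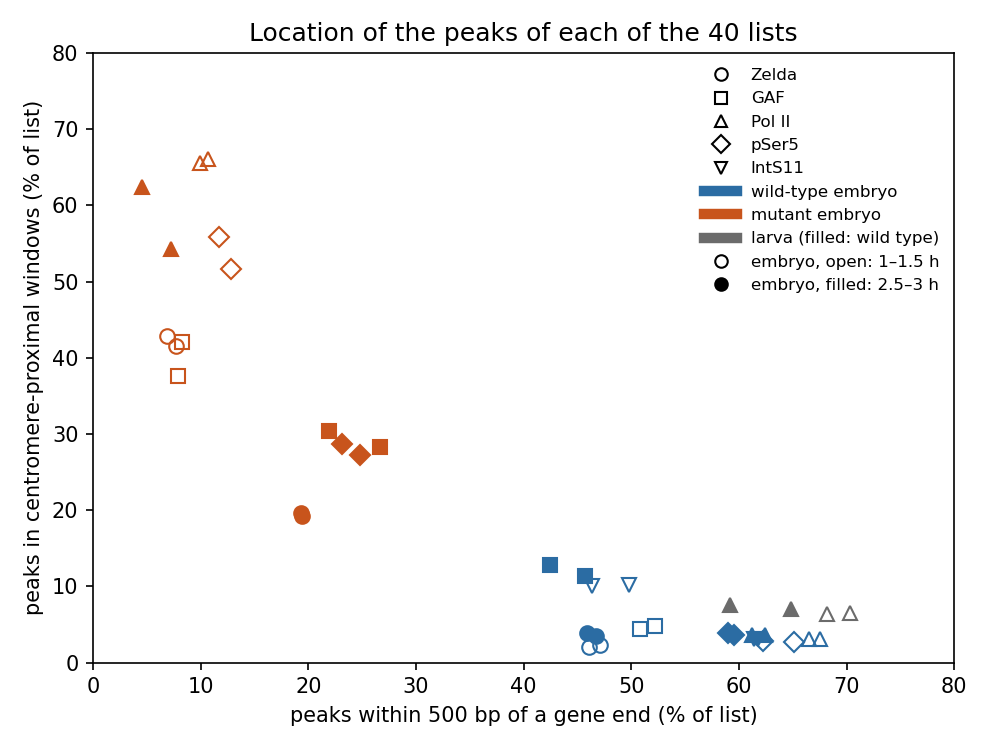
Each of the 40 lists by its share of peaks within 500 bp of a gene end (x axis, %) and in the centromere-proximal windows (y axis, %), with blue for wild-type embryos, orange for mutant embryos, grey for larvae and a symbol per antibody. Mutant embryo lists lie between 4.51% and 26.7% on the x axis and wild-type embryo lists between 42.4% and 67.5%.

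The regions that mutant embryos gained seldom lay at gene ends, and many were shared between antibodies. Gained regions made up 95.2% of the mutant Pol II regions at 2.5–3 h and 20.2% of the mutant GAF regions at 2.5–3 h, the highest and lowest of the 8 comparisons. Of gained regions, 2.34% to 6.51% lay near gene ends, 28.7% to 43.6% inside genes and 49.9% to 66.9% outside them, 44.9% to 72.4% in the centromere-proximal windows and 6.97% to 12.8% on the Y chromosome, against 0% to 0.276% of lost regions on the Y. The longest, picked after their values were seen, were X 23377343–23394765 for Pol II at 2.5–3 h (17423 bp) and for pSer5 at 1–1.5 h X 23377346–23394755 (17410 bp), and neither had an annotated gene within 500 bp. At 1–1.5 h, 98.6% of the regions gained for Zelda carried a mutant peak of 3 or 4 of the antibodies, and 34.5% of those gained for pSer5. Regions with all 4 antibodies numbered 2474 in wild-type embryos at 1–1.5 h, 79.6% of them near gene ends, and 782 in mutant embryos, 4.48% of them near gene ends. Mutant Pol II peaks at 2.5–3 h overlapped mutant pSer5 peaks by 57.1% and wild-type Pol II peaks by 3.95%. Genes with gained peaks numbered 17, 37 and 106 for Zelda, GAF and Pol II at 1–1.5 h and 28, 28, 59 and 114 for Zelda, GAF, Pol II and pSer5 at 2.5–3 h. They were most for pSer5 at 1–1.5 h, where the count with all lists was lower than each count without a single library. That order holds by construction, since leaving out a list loosens the rule for gained genes and regions. For pSer5 at 1–1.5 h the counts without a single library were 374 without mutant replicate 1, 319 without mutant replicate 2 and at least 215 in every case. Without single libraries the other embryo comparisons reached at most 189, for Pol II at 2.5–3 h without mutant replicate 1. Cyp6a8, a cytochrome P450 gene, gained Pol II peaks of 3424 and 3528 bp at 2.5–3 h and pSer5 peaks of 3533 and 3426 bp at 1–1.5 h. Hecw, a ubiquitin ligase gene, gained GAF peaks of 2741 and 2721 bp at 1–1.5 h, Zelda peaks of 1365 and 1249 bp at 2.5–3 h and Pol II peaks of 2779 and 2281 bp at 2.5–3 h. Several neighbouring copies of Ste on X ranked among the named gained genes for Zelda at 1–1.5 h and GAF at both stages. At Ste:CG33239 the GAF peaks measured 2012 and 1461 bp at 1–1.5 h. Copies of the histone gene His1 ranked so for Zelda at 2.5–3 h. Whether reads could be placed in these copies was not tested. The gained regions of GAF at 2.5–3 h numbered 596, with 2172 without mutant replicate 1 and 919 without mutant replicate 2. Without single libraries those of Zelda reached 2130 in place of 1231 and 1780 in place of 872 at the 2 stages, those of GAF at 1–1.5 h 4091 in place of 2302, those of Pol II 7737 in place of 5101 and 5627 in place of 3371, and those of pSer5 10742 in place of 7535 and 5578 in place of 3533.

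**Figure D4:**
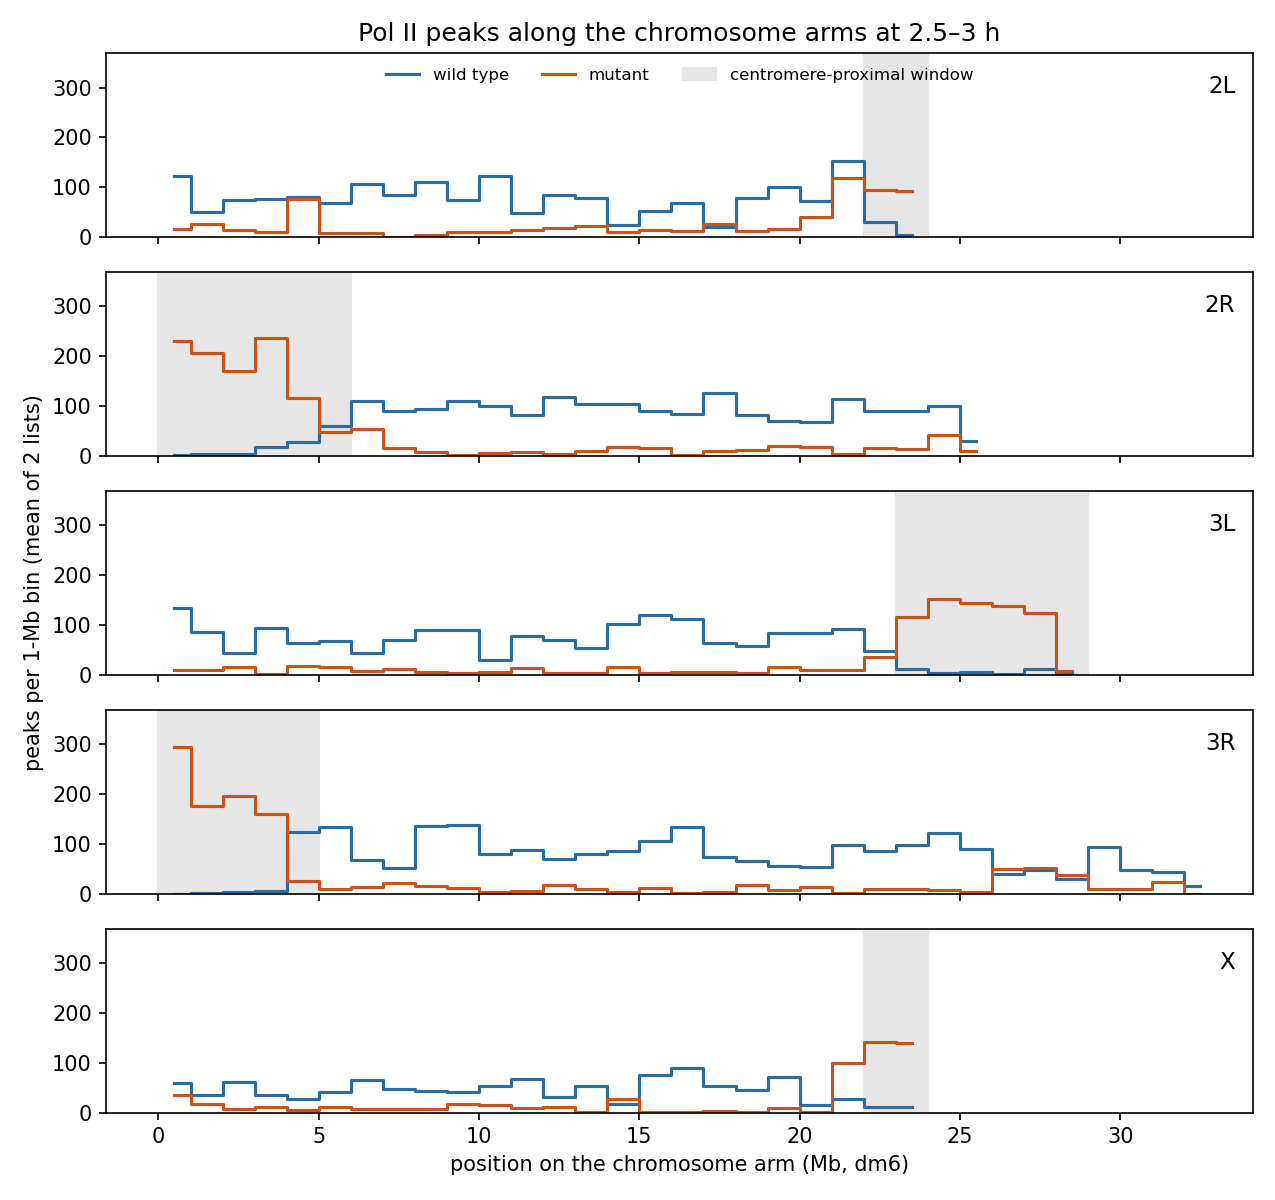
Pol II peaks per bin of 1 Mb (y axis, mean of 2 lists) along 5 chromosome arms (x axis, Mb) in wild-type (blue) and mutant (orange) embryos at 2.5–3 h, with the centromere-proximal windows in grey. The windows hold 58.4% of mutant and 3.62% of wild-type peaks.

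IntS11 peaks lay at many more genes at 2.5–3 h than at 1–1.5 h in wild-type embryos. Its peaks numbered 1343 ± 94.8 at 1–1.5 h and 6308.5 ± 344 at 2.5–3 h (SD, n = 2 lists each, exact permutation p = 0.333, the smallest possible), 4.70-fold more. Genes with IntS11 at an end numbered 663, then 5198, and 657 of the 663 were bound at both stages. Early genes with IntS11 included slam (4459 and 4162 bp, then 4750 and 4727 bp) and Sry-alpha, a cell-formation gene (3417 and 2476 bp, then 4314 and 4561 bp). At the glycolysis gene Pgk the peaks lengthened from 1493 and 1859 bp to 10413 and 10776 bp. At 2.5–3 h IntS11 was gained at HnRNP-K (5707 and 5744 bp) and Hrb27C (5675 and 5296 bp), genes for RNA-binding proteins, and at the chromatin protein gene HmgD (4780 and 5602 bp). Early IntS11 lay at 19 of 29 spliceosomal snRNA genes (Fisher's exact test, odds ratio 39.1, adjusted p = 6.46e-18), 110 of 111 histone genes (adjusted p = 8.92e-148), 7 of 9 pair-rule genes (adjusted p = 6.62e-08), 9 of 15 Notch target and Bearded genes (adjusted p = 3.29e-08) and 8 of 17 earliest zygotic genes (adjusted p = 1.32e-06). Ribosomal protein genes had it at 8 of 85 early, and 57 gained it later (odds ratio 12.9, adjusted exact p = 2.73e-19). No cuticle and no gut enzyme gene gained it (Fisher's exact test, odds ratio 0.0703 and 0.0566, adjusted p = 0.035 and 0.0136). Of the early regions 87.7% were kept, 51.6% when both stages were held to lists of equal length, and with such lists the 3619 gained regions became 304 and the 91 lost ones 309. The 2 early lists overlapped by 65.5% and the 2 late ones by 81.0%. The 91 regions lost with time lay near gene ends at 2.2% and in the centromere-proximal windows at 56.0%. They numbered 162 without early replicate 1 and 217 without early replicate 2, where the looser rule raises the count by construction.

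Genes with IntS11 in wild type carried the other 4 proteins far more often than genes without it. At 1–1.5 h, 97.8% of 633 protein-coding genes with IntS11 had Pol II, against 43.7% of the rest (odds ratio 55.1, Fisher's exact test p = 3.62e-191), and 96.1% had Zelda, against 43.4% (odds ratio 31.1, p = 1.03e-175). At 2.5–3 h the odds ratios over 5124 genes with IntS11 were 77.9 for Pol II, 141 for pSer5, 30.1 for Zelda and 14.7 for GAF. In mutant embryos at 1–1.5 h, genes with IntS11 lost Pol II in 40.5% of cases and other Pol II genes in 87.7% (odds ratio 0.0953, adjusted exact p = 2.39e-151). For Zelda these shares were 78.6% and 97.6% (adjusted exact p = 1.07e-66), for GAF 67.8% and 91.5% (adjusted p = 4.63e-49) and for pSer5 54.2% and 79.3% (adjusted p = 1.22e-41). At 2.5–3 h they were 79.9% and 92.8% for Zelda (adjusted exact p = 2.57e-36) and 55.8% and 79.6% for pSer5 (adjusted p = 8.82e-119). GAF at 2.5–3 h went the other way, with 68.5% and 60.6% (odds ratio 1.41, adjusted p = 3.84e-06), but not without wild-type replicate 2 (log2 odds ratio 0.02, Fisher's exact p = 0.866) or mutant replicate 2 (0.20, p = 0.0747). Pol II at 2.5–3 h gave 95.4% and 97.3% (odds ratio 0.579, adjusted exact p = 8.69e-05), and without the 111 histone genes, which all kept it, 97.6% and 97.3% (odds ratio 1.12, adjusted exact p = 0.470), while within quartiles of wild-type peak length it did not pass either (log2 odds ratio −0.41, p = 0.0852, against −0.79) and was −1.63 without mutant replicate 2. Without histone genes the shares for Pol II at 1–1.5 h were 48.8% and 87.8% (odds ratio 0.133, adjusted exact p = 5.58e-93), and the other 6 tests kept their direction and passed. Genes are not replicates, so these tests describe these lists.

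**Figure D5:**
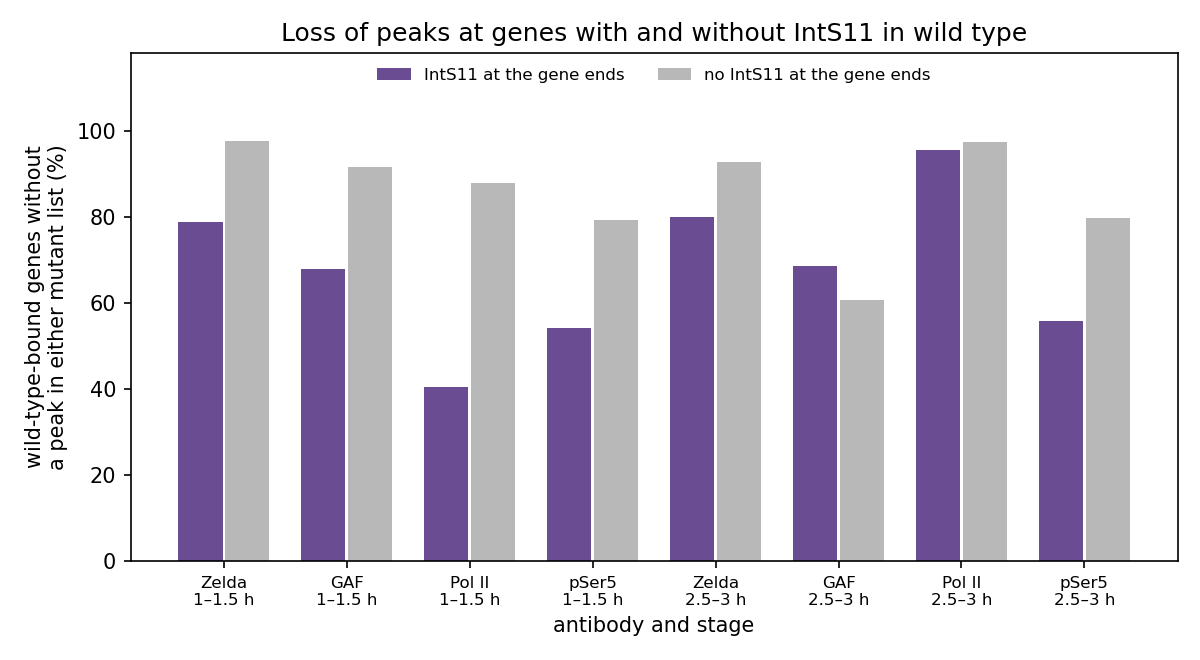
Share of the genes bound in wild type that had no peak in either mutant list (y axis, %), for genes with (purple) and without (grey) IntS11 in wild type of the same stage, by antibody and stage (x axis). Pol II at 1–1.5 h shows 40.5% against 87.7%, and GAF at 2.5–3 h 68.5% against 60.6%.

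Wild-type embryos kept most binding sites between the stages. Pol II kept 92.2% of its 1–1.5 h regions and pSer5 94.9%, GAF kept 84.5% and Zelda 74.1%. Pol II peaks were more numerous by 0.32 ± 0.07 on the log2 scale and GAF peaks by 0.46 ± 0.11 (SE, n = 2 lists each, exact permutation p = 0.333, the smallest possible), while Zelda changed by −0.06 ± 0.08 and pSer5 by 0.09 ± 0.10 (exact permutation p = 0.667). With time GAF was gained at Hr3, an ecdysone response gene (2609 and 3001 bp), and Zelda at RhoGEF64C, a gene for cell shape regulation (7295 and 7399 bp). Ribosomal protein genes gained GAF at 8 genes (Fisher's exact test, odds ratio 7.92, adjusted p = 0.00121) and Zelda at 3 (adjusted p = 0.0229), and dorsoventral genes gained GAF at 3 (adjusted p = 0.0388).

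In larvae labelled 48AEL, zygotic mutants kept most Pol II regions of wild type. Of 4457 regions 77.4% were kept, and the lists held 6945 ± 1769 peaks in wild type and 6444.5 ± 647 in the mutant (SD, n = 2 lists each, log2 ratio −0.09 ± 0.28 SE, exact permutation p = 1). Without wild-type replicate 2 the kept share was 49.9%, and without wild-type replicate 1 the log2 ratio was 0.17. Peaks near gene ends made up 62.0% and 69.3% of the lists. By genotype 446 regions were lost and 309 gained, and other ways to part the 4 lists into pairs gave up to 583, so these counts do not stand out from the spread between lists. Without single libraries lost regions reached 2550 (without wild-type replicate 2) and gained ones 1495 (without mutant replicate 1). Leaving out a list loosens the rule, so these counts and those of genes below rise by construction. Of 5022 genes, 132 lost Pol II and 4430 kept it, and 251 gained it. Lost genes numbered 288 and 635 without wild-type replicates 1 and 2, and 264 and 460 without mutant replicates 1 and 2. Gained genes numbered 916 without wild-type replicate 1, and 712 and 526 without mutant replicates 1 and 2. E(spl)m8-HLH, a Notch target, lost peaks of 1202 and 1182 bp, loco, a gene for G-protein signalling in glia, lost peaks of 724 and 859 bp, and ey, an eye development gene, gained peaks of 725 and 2085 bp. At Pgk and Bacc peaks of 5596 and 5547 bp measured 5376 and 2885 bp. Ribosomal protein genes kept Pol II at 80 of 80, glycolysis genes at 11 of 11, fat body genes at 6 of 6 and heat shock genes at 14 of 17. Loss differed for 0 of 26 gene lists by Fisher's exact test, and for 0 at an unadjusted p under 0.05. Of the 18 muscle genes listed, 3 gained Pol II (Fisher's exact test among genes not bound in wild type, odds ratio 27.7, adjusted p = 0.0206). The larval mutant differed in stage, tissue and genotype from the embryonic one, and the difference between them was not tested.

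Genes that lost pSer5 in mutant embryos were longer than those that kept it, and for Pol II the direction at 1–1.5 h depended on histone genes. Of the kept genes 111 were histone genes in each embryo comparison, and none of the lost ones. Without them the median length for pSer5 was 2883.5 bp for lost and 2138 bp for kept genes at 1–1.5 h (permutation over genes, adjusted p = 2.5e-05) and 2781 and 2245 bp at 2.5–3 h (permutation over genes, adjusted p = 2.5e-05). For Pol II at 2.5–3 h it was 2670.5 bp for lost and 595 bp for 146 kept genes (permutation over genes, adjusted p = 1.67e-05), and 1713 bp for the 35 kept genes other than histone genes (adjusted p = 0.00323). At 1–1.5 h lost Pol II genes measured 2714 bp and kept ones 2248.5 bp (permutation over genes, adjusted p = 7.5e-05), but 3103 bp without histone genes (adjusted p = 0.0316). In larvae lost genes were the shorter ones, 2347.5 against 3110 bp (permutation over genes, adjusted p = 0.0311).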

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

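The tests of lower depth (except for Zelda and GAF regions lost), of genome build, of background shared between antibodies and of joined intervals as the source of higher peak numbers or of gained regions were chosen after the results were seen.

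Mutant Pol II lists held more peaks than wild-type lists at 1–1.5 h, a log2 ratio of 0.20, and fewer at 2.5–3 h, a log2 ratio of −0.85. Both mutant lists lay above both wild-type lists at 1–1.5 h and below them at 2.5–3 h. Permuting genotypes within stages gave an exact p of 0.0556 for the difference of −1.05, the smallest that 36 orders can give. Its null is no genotype effect at either stage, so it does not by itself show a difference between them. With joined intervals the ratio at 1–1.5 h was −0.081, so the surplus of Pol II intervals there may come from the shorter gaps and minimum lengths of the mutant lists, and for pSer5 at 1–1.5 h, where the ratio became −0.31, the same holds. With joined intervals the difference between stages was −1.40 (exact permutation p = 0.278).

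Regions gained in mutant embryos lay at gene ends in at most 6.51% of cases and near centromeres in 44.9% to 72.4%, and lower depth of the mutant libraries would only remove peaks, whereas in each of the 8 comparisons gained regions numbered at least 3.63 times the highest count from other ways to part the 4 lists. Joined intervals lowered the number of gained regions, from 3371 to 1999 for Pol II at 2.5–3 h, but their share of mutant regions by at most 8.76% of its value in the 8 comparisons, and another genome build is excluded, as overlap with mutant GAF lists of 2.5–3 h exceeded the highest of shifted copies by at least 3.76 points on each of 5 arms, for wild-type GAF of that stage and the 7 other mutant groups. A background that all antibodies bring down in mutant chromatin could not be settled, as 59.4% to 98.6% of gained regions of Zelda and GAF and 34.5% to 47.7% of those of Pol II and pSer5 carried 3 or 4 antibodies, while 61.7% to 91.3% of lost regions did in wild type. The background would also be in wild-type chromatin where enrichment is low, and of the 91 wild-type IntS11 regions present only at 1–1.5 h, 95.6% overlapped a mutant peak of that stage, so weak enrichment over such a background may explain gained regions in part. A change of the mutant chromatin itself is confounded with the genotype and was not tested, nor was a wrong label or a wrong control library in peak calling.

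Regions lost in mutant embryos fall into separate cases. For Pol II and pSer5 at 1–1.5 h, which kept at most 12.5% of wild-type regions, the mutant lists held more peaks as deposited (log2 ratios 0.20 and 0.41). They held fewer with joined intervals (−0.081 and −0.31) and with peaks of at least 500 bp (−0.078 and −0.42), so lower depth is not excluded. On the arms the ratios were −1.59 and −0.81, but leaving out the centromere-proximal windows lowers mutant numbers by construction. For Pol II at 2.5–3 h, at most 6.91% of the longest 10% of wild-type regions had a peak in a mutant list. That is below the limit of 10%, set after the results were seen, and argues against lower depth alone. Length stood in for strength and depth was unknown, so lower depth is not excluded there. A failed enrichment was not tested. For pSer5 at 2.5–3 h 71.6% of the longest 10% were kept, and lower depth or weaker enrichment may explain the loss. This share cannot decide it, since long regions also meet a mutant peak more often by position alone. No chance level was drawn for the longest 10%. For Zelda and GAF the kept share of the longest 10% was 28.4% and 49.5% at 1–1.5 h, between the 10% and 50% set in advance. At 2.5–3 h it was 66.6% and 87.9%, above the 50% set for lower depth or weaker enrichment. The same limit of length holds here. Lower depth, weaker enrichment and a true loss of binding cannot be told apart without reads. Loss of binding through the genotype stays open and untested in all 8 comparisons, since every mutant library shares it.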

How the results depend on the processing

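Alternatives with joined intervals, peaks of at least 500 bp, chromosome arms alone, lists of equal length, whole genes, quartiles of peak length, and histone genes or single replicates left out of gene-level tests were chosen after the data were seen. The cause was not tested for any change below.

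The log2 ratio of Pol II peaks at 1–1.5 h (0.20) reversed to −0.081 with joined intervals, −0.078 with peaks of at least 500 bp and −1.59 on the arms. That of pSer5 at 1–1.5 h (0.41) reversed to −0.31, −0.42 and −0.81, and that of pSer5 over both stages (0.19) to −0.47, −0.69 and −0.66. The joint ratio of Pol II and pSer5 (−0.07) passed the exact permutation test at −0.63 (p = 0.00309), −0.79 (p = 0.00309) and −1.34 (p = 0.00154). Ratios on the arms are lower by construction, since the windows left out were chosen after the peaks were seen and held more of the mutant peaks. Leaving out single lists gave −0.35 to 0.17 for larvae, with 0.17 without wild-type replicate 1 and 0.01 without mutant replicate 1, −0.12 to 0.0032 for Zelda between stages, turning without late replicate 1, and −0.0011 to 0.19 for pSer5 between stages, turning without early replicate 1. The Zelda and GAF ratios of mutant over wild type kept their sign in every setting, and the joint ratio of both factors kept its side of 0.05. For 1 factor over both stages no exact permutation p can fall below 0.0556.

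Counts of lost and gained regions moved with the setting, as for IntS11 between stages, where lists of equal length gave 304 gained in place of 3619 and 309 lost in place of 91, and for Zelda at 1–1.5 h, with 1547 lost in place of 8207. The share of wild-type regions kept is given below where it moved by at least the SD between the 2 lists of the second group. With overlap of 50% it was 9.76% for Pol II and 6.77% for pSer5 at 1–1.5 h, 16.9% for pSer5 at 2.5–3 h, and between stages 84.1% for GAF and 94.4% for pSer5. With a peak in either list of the second group it was 8.62% and 21.9% for Zelda at the 2 stages, 17.3% and 44.4% for GAF, 17.8% and 2.2% for Pol II, 16.9% and 29.3% for pSer5 and 90.0% in larvae, and between stages 85.7% for Zelda, 92.1% for GAF, 96.2% for Pol II, 97.3% for pSer5 and 89.5% for IntS11. With lists of equal length it was 16.8% and 32.1% for Zelda, 52.9% for GAF at 2.5–3 h, 10.9% for Pol II at 1–1.5 h, 7.14% and 21.02% for pSer5, and between stages 74.1% for GAF, 85.9% for Pol II, 94.2% for pSer5 and 51.6% for IntS11. With joined intervals it was 4.62% for Zelda, 11.005% for Pol II and 6.97% for pSer5 at 1–1.5 h and 17.5% for pSer5 at 2.5–3 h. On the arms it was 84.1% for GAF and 93.8% for IntS11 between stages.

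Replicate numbers as a block gave 5.66% for Zelda at 1–1.5 h, 21.4% for pSer5 at 2.5–3 h and 65.6% in larvae, and between stages 83.4% for GAF, 87.6% for Pol II, 91.5% for pSer5 and 84.5% for IntS11. Differences between replicates 1 and 2 did not correlate between the 2 groups of a comparison (correlations of −0.047 to 0.023). Few regions were shared between genotypes, which alone keeps this value near 0 there. Lists of different antibodies were not compared, so whether samples with the same number share chromatin stays unknown.

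Without single replicates the kept share ranged from 4.07% to 7.23% and 10.4% to 20.0% for Zelda at the 2 stages, 10.4% to 16.5% and 26.7% to 43.7% for GAF, 10.3% to 16.1% and 0.939% to 2.12% for Pol II, 6.86% to 13.8% and 17.5% to 25.2% for pSer5, and 49.9% to 86.1% in larvae. Between stages it ranged from 63.7% to 82.1% for Zelda, 75.8% to 88.4% for GAF, 82.0% to 94.8% for Pol II, 86.9% to 96.2% for pSer5 and 81.8% to 88.8% for IntS11. Values moved by over 1.5 times without mutant replicate 1 for Pol II at 2.5–3 h (2.12%) and pSer5 at 1–1.5 h (13.8%), and without wild-type replicate 2 in larvae (49.9%).

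Loss at IntS11 genes (log2 odds ratio) no longer passed for Pol II at 2.5–3 h within quartiles of peak length (−0.41 against −0.79), reversed to 0.17 there without histone genes (adjusted exact p = 0.470), and ranged from 0.019 to 0.80 for GAF at 2.5–3 h without single replicates (0.50 with all), with 0.019 without wild-type replicate 2 and 0.20 without mutant replicate 2. The other 84 alternatives of these tests stayed on their side of 0.05, as did all 48 for co-occupancy. Of 60 gene-list calls of loss, 44 passed under each of 8 settings and 16 did not under at least 1. Several lists share genes, so these calls are not independent.

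The share of peaks near gene ends and in the centromere-proximal windows stayed past the threshold in each of 32 fits without 1 library, from −41.4 to −40.8 and from 37.1 to 38.1 points. Counts of gained genes moved by over 1.5 times in 48 alternatives and by less in 64, and counts of lost genes in 25 and 87. Part of these alternatives left out a list, which loosens the rule and raises such counts by construction.

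Not run were −log10 q of at least 5, equal lists by q, motif windows, genes with 2 kb upstream, quartiles of fold enrichment and strength by q, since the lists hold no such columns and the gene table no strand.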

Other observations

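Every wild-type embryo list and every larval list held an interval on the mitochondrial genome, and 4 of the 16 mutant embryo lists did. Mutant embryo lists placed 4.13% to 11.1% of their peaks on the Y chromosome, wild-type embryo lists 0.0257% to 1.28% and larval lists 0.0527% to 0.171%. At IntS11 regions of wild-type embryos, Pol II peaks of the same stage overlapped 77.4% at 1–1.5 h in wild type and 52.8% in the mutant, and 88.9% and 3.61% at 2.5–3 h, where shifted lists gave 4.97%. At histone genes the longest interval of all lists, 53781 bp, was the Pol II peak of mutant embryos at 1–1.5 h.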
